A study of Agrobacterium sp. CGMCC 11546 with 9 samples.

How the data were processed

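Total RNA was taken after 24 h of fermentation from 3 strains of *Agrobacterium* sp. CGMCC 11546 with 3 libraries each, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2, a short read aligner, and HTSeq, a read counter, without their roles. The genome build, the annotation, the strand setting and any filter were not given in the sources used here. Each library had its own deposited table of 5457 IDs with RPKM values, made by the authors, so values are relative to gene length and to the total reads of the library. No columns of other samples were present. RPKM scales each library by its total, so a few abundant transcripts can shift all others, and this was examined with other scalings.

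The depth was recovered from the RPKM values. Values of an ID are whole multiples of what 1 read is worth in each library, and the ratios of these steps gave the totals, which were all within 0.0002 of a whole number. A length was then chosen for each ID at which its values came out as whole reads within a tolerance of 0.01. All of the values checked, 100%, did, which follows from the rule by which lengths were chosen. An ID with no such length would be left out of this check and of the recovered reads. Of the 4440 IDs above 0 in at least 8 libraries, 99.2% had lengths divisible by 3, with a median of 870 bp, so lengths are called coding lengths. Tested on simulated reads, the procedure returned 9 of 9 totals exactly. It returned 99.8% of lengths and 99.9% of read numbers over 4477 IDs with reads in most libraries. Recovered reads were used for depth, for read shares, for counting intervals and for an added alternative test, and RPKM remained the unit of every main result. The listed IDs held 99.4 to 99.9% of each total.

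Groups were taken from the genotype labels. Before the data were examined, the tests, the rule for the named IDs and 30 gene lists were fixed. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), two-sided, with 1 fit of 3 group means to all 9 libraries, a mean-variance trend and Benjamini-Hochberg adjustment over the 4488 IDs with a mean RPKM of at least 1. A call is an adjusted p under 0.05. Fold changes on the log2(RPKM + 1) scale understate the change of low IDs, so folds of named IDs are ratios of mean RPKM. Intervals of folds of summed reads come from exact binomial limits at 95%. Other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

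The limma step was tested on simulated reads for 4488 genes with a dispersion of 0.02 and 50 genes changed at each size. At 2-fold it recovered 92% for the metH comparison, 90% for the metZ comparison and 80% between the mutants, at 4-fold 100%, 98% and 98%, and at 1.5-fold 52%, 42% and 34%. Of 4288 unchanged genes 12, 12 and 3 were called. No simulated library stood apart from its group as wild type replicate 3 does (see Results). These rates therefore do not describe the real fit, above all at low levels.

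As the files do not pair IDs with names, the named IDs are the 2 with the largest rise and the 2 with the largest fall on the log2 scale in each comparison, among called IDs whose libraries did not overlap between the groups. For the same reason 0 of the 30 gene lists, among them curdlan synthesis, methionine synthesis and transport, sulfate assimilation and nitrogen regulation, could be matched. No list result and no level of metH or metZ is given by name, the genotypes rest on the labels, and a named ID can be a deleted gene itself. Overlapping and repeated genes could not be separated without an annotation.

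Alternatives were pseudocounts of 0.1 and 5, no filter and a mean RPKM of at least 10, TMM factors (own code, trimming 30% of ratios and 5% of levels), median of ratios scaling, quantile normalization, rescaling to TPM, fits of the compared groups only, a replicate block, no trend, limma arrayWeights, a minimum of 2-fold and leaving out each library. Added after the data were seen were limma voom on recovered reads, leaving out the 10 most abundant IDs with rescaling, that and median of ratios scaling without wild type replicate 3, and the overlap of the mutants under TMM and median of ratios scaling. Runs of consecutive IDs were compared with shuffled orders in sets of 1000, and IDs grouped by leading digit were tested with camera of limma, both added after the data were seen. The agreement of the mutants was set against 100 draws of simulated unchanged groups.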

Results

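Transcript levels were measured by RNA sequencing in *Agrobacterium* sp. CGMCC 11546, a soil bacterium that secretes curdlan, a linear beta-1,3-glucan polysaccharide. Cells of the wild type strain, of a metH deletion mutant and of a metZ deletion mutant were sampled after 24 h of curdlan fermentation, with 3 biological repeats per strain according to the submitters' design, giving 9 libraries. By textbook knowledge metH encodes methionine synthase, which methylates homocysteine to methionine, and metZ encodes a sulfhydrylase that forms homocysteine from an activated homoserine. The title of the series places both genes in methionine biosynthesis and links them to curdlan synthesis, so the question was which transcripts differed from the wild type in each mutant and whether the mutants differed from each other. Values were RPKM, reads per kilobase of gene scaled to the total reads of the library, for 5457 locus IDs. The files do not pair IDs with gene names and no table of names was used here, so transcripts are given by ID, the genomic positions of the IDs are not given, and the deleted genes themselves were not looked up.

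The libraries held 6229626 to 8075395 reads each, as recovered from the steps between low RPKM values. At least 1 library showed reads for 4541 IDs, and 916 IDs were listed at 0 in all 9 libraries. At these depths a count of 0 allowed up to 3 reads, which for a transcript of 1 kb corresponded to 0.371 to 0.482 RPKM. Such limits and the intervals on folds given with read numbers cover counting error only. Replicates differed by more than sampling noise in every pair, so no library was counted as a repeat of another. Pearson correlations of log2 values across IDs within a group were 0.9899 to 0.9948 for every pair without wild type replicate 3, and 0.927 for that library against either of the other wild type libraries. Its lower quartile was 16.4 RPKM and its median 43.0 RPKM, whereas the other 8 libraries had lower quartiles of 1.86 to 2.71 RPKM and medians of 18.1 to 24.9 RPKM. The counts of calls against the wild type are therefore given with and without that library.

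**Figure D1:**
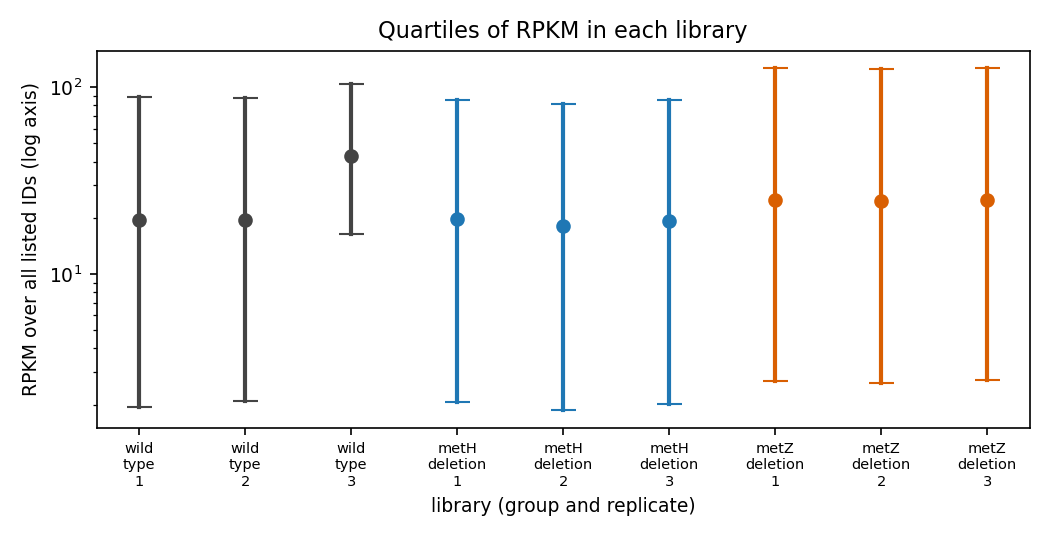
RPKM on a log axis in each of the 9 libraries, with a point at the median and a bar from the lower to the upper quartile over all listed IDs; colours mark the strain. The lower quartile of wild type replicate 3 lies at 16.4 RPKM, and those of the other 8 libraries lie between 1.86 and 2.71 RPKM.

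In the metH deletion mutant, the 2 IDs with the largest rises were Atu3419 and Atu4642. Atu3419 (coding length 1188 bp) rose from 471 ± 25.1 RPKM in the wild type to 3025 ± 106 RPKM (SD, n = 3 each), 6.42-fold. Atu4642 (2172 bp) rose 5.80-fold, from 372 ± 6.22 to 2157 ± 31.0 RPKM. The largest fall was that of Atu2155 (3774 bp), from 179 ± 7.47 RPKM to 0.843 ± 0.345 RPKM, 213-fold lower. It was covered by 12 to 35 reads in each metH deletion library and by 4181 to 5455 reads in each wild type library, and the ratio of summed reads, scaled to the totals, was 207-fold (exact 95% interval 164 to 266). The next largest fall on the log2 scale was that of Atu4005 (74 bp), which had no read in any metH deletion library and 5, 1 and 25 reads in wild type replicates 1, 2 and 3. At a floor of 3 reads per library this was at least 3.69-fold lower, a bound that rests on wild type replicate 3: without it the wild type mean was 5.46 RPKM, under the floor of 5.71 RPKM, and no fold is given. The rank of Atu4005 rests on wild type replicate 3 too. Without that library its log2 fold change was -2.39, while 2 IDs were called at least 8-fold lower on the log2 scale.

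Across the 4488 IDs tested with limma on log2(RPKM + 1), 282 were higher and 892 lower in the metH deletion than in the wild type at the adjusted p threshold of 0.05. At least 2-fold changes were seen in 96 of the higher and 128 of the lower IDs, and at least 8-fold changes in 0 and 3, with 6 of the latter kind without wild type replicate 1 and 8 with a pseudocount of 0.1. This 2-fold split turned with the scaling, to 179 higher and 40 lower under TMM and 160 and 48 under median of ratios, and it was 101 and 201 without wild type replicate 1, 98 and 188 without replicate 2 and 122 and 107 without replicate 3. Of the 943 IDs with a mean of 200 RPKM or more, 178 were higher and 431 lower, and of the 1150 IDs between 50 and 200 RPKM 96 were higher and 347 lower, or 208 and 368 without wild type replicate 3. Of the 1453 IDs between 10 and 50 RPKM, 8 were higher and 107 lower, or 142 and 193 without that library. Of the 942 IDs below 10 RPKM, 0 were higher and 7 lower, and without wild type replicate 3, which stood above the other wild type libraries by the largest ratio at these levels, 22 were higher and 26 lower. The 282 higher IDs took 12.9 ± 0.208% of the reads in the wild type and 33.1 ± 0.0836% in the metH deletion (SD, n = 3), and the 892 lower IDs took 47.7 ± 0.458% and 28.5 ± 0.839%. These shares describe IDs that were chosen by their change. The log2 fold changes were 2.68 (SE 0.06) for Atu3419, 2.53 (SE 0.05) for Atu4642 and -6.63 (SE 0.15) for Atu2155, each with a limma adjusted p of 5.2e-11. For Atu4005 the log2 fold change was -3.51 (SE 0.89, limma adjusted p = 0.010). As its reads in the metH deletion were 0, the value for Atu4005 follows the pseudocount, and it was -6.58 with a pseudocount of 0.1. The call ended with a pseudocount of 5 (-1.82, adjusted p = 0.054) and with limma voom on recovered reads (-3.46, adjusted p = 0.129), and its log2 fold change was -2.39 without wild type replicate 3 and -4.55 without wild type replicate 2, over a range of adjusted p from 0.00075 to 0.129 in all alternatives.

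Without wild type replicate 3, 556 IDs were higher and 1037 lower in the metH deletion, 270 and 874 of them shared with the calls from all libraries, and the median log2 fold change over all tested IDs moved from -0.38 to -0.07. The split by direction turned to 577 higher and 199 lower under TMM scale factors and 386 and 192 under median of ratios scaling, and was 585 and 700 after quantile normalization, at medians of 0.0030, -0.05 and -0.02. These factors were estimated with wild type replicate 3 included. Median of ratios scaling without that library gave 743 higher and 847 lower, so under this scaling the turn rested on that library. TMM was not run without it. Atu3419, Atu4642, Atu2155 and Atu4005 kept their direction under each of these scalings and without wild type replicate 3.

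In the metZ deletion mutant the largest rises and falls were larger than in the metH deletion mutant. Atu1866 (195 bp) rose from 42.0 ± 7.85 RPKM in the wild type to 12080 ± 790 RPKM (SD, n = 3 each), 288-fold. Atu1865 (237 bp), with the number next to it, rose 204-fold, from 94.7 ± 10.9 to 19342 ± 952 RPKM. Atu1468 (975 bp) fell 1377-fold, from 60016 ± 4303 RPKM to 43.6 ± 2.85 RPKM, which moved its share of all reads from 5.85 ± 0.420% to 0.0043 ± 0.00028%. Atu0432 (1185 bp) fell from 942 ± 55.6 RPKM to 0.503 ± 0.0843 RPKM, 1875-fold. It had 3 to 5 reads in each metZ deletion library and 7646 to 8970 in each wild type library, and its ratio of summed reads, scaled to the totals, was 1847-fold (exact 95% interval 1080 to 3470). As the deleted genes were not looked up, it is left open whether Atu0432 here, or Atu2155 in the metH deletion, is the deleted gene itself, in which case its fall is the deletion and not a response to it.

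By limma, 1441 IDs were higher and 932 lower in the metZ deletion than in the wild type. Of these, 890 and 591 differed at least 2-fold, and 60 and 85 at least 8-fold. Without wild type replicate 3 these numbers were 1288 and 531 at 2-fold and 89 and 84 at 8-fold. The 1441 higher IDs took 26.4 ± 0.549% of the reads in the wild type and 68.4 ± 0.921% in the metZ deletion, while the 932 lower IDs took 54.3 ± 0.788% and 15.7 ± 0.245% (SD, n = 3), shares that again describe IDs chosen by their change. Between 50 and 200 RPKM, 659 of 1150 IDs were higher and 255 lower, and at 200 RPKM or more 489 of 943 were higher and 343 lower. Between 10 and 50 RPKM, 280 of 1453 were higher and 295 lower, or 743 and 327 without wild type replicate 3. Below 10 RPKM, 13 of 942 were higher and 39 lower, which turned to 270 higher and 77 lower without wild type replicate 3. The log2 fold changes were 8.15 (SE 0.16, limma adjusted p = 7.1e-13) for Atu1866, 7.66 (SE 0.13, 1.9e-13) for Atu1865, -10.39 (SE 0.11, 9.0e-15) for Atu1468 and -9.29 (SE 0.08, 3.3e-15) for Atu0432. Without wild type replicate 3, 2239 IDs were higher and 1019 lower, 1433 and 923 of them shared with the calls from all libraries, and the median log2 fold change moved from 0.04 to 0.40. Median of ratios scaling gave 1273 higher and 1184 lower, with 764 and 771 at least 2-fold and a median of -0.12.

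**Figure D2:**
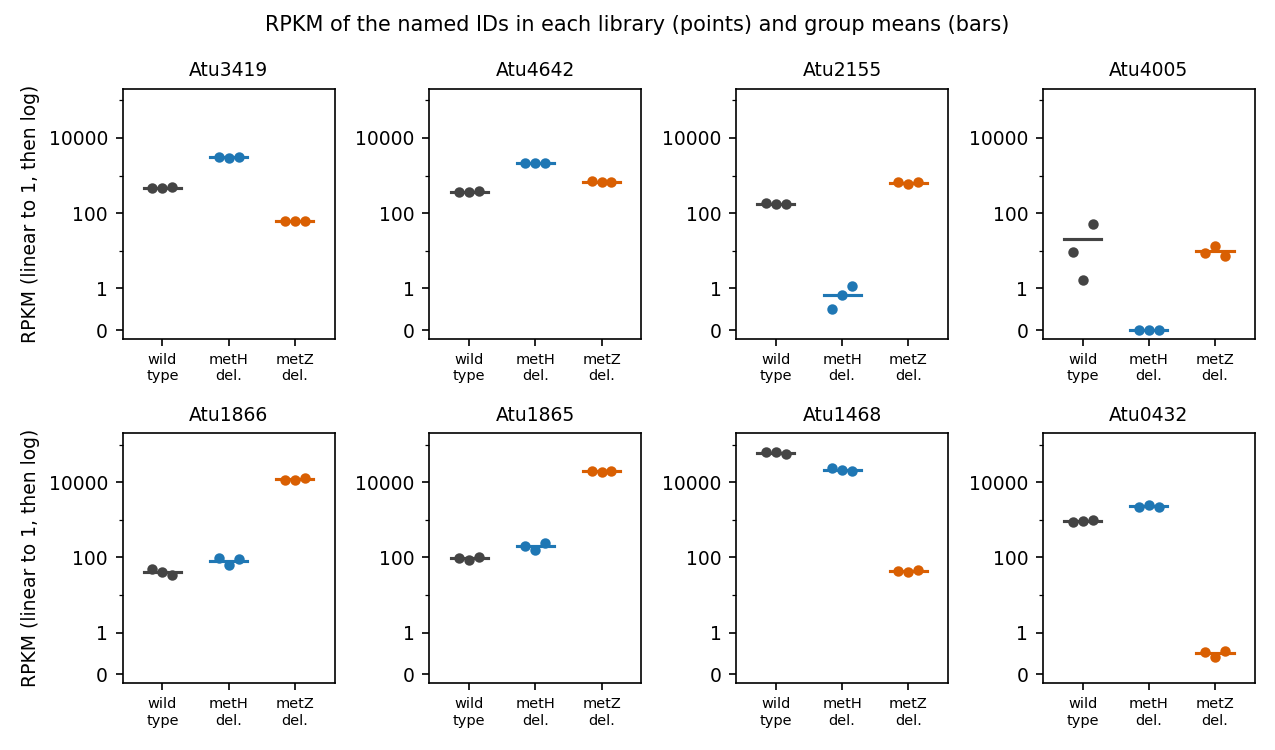
RPKM of the 8 named IDs in each library (points) and the mean of each strain (horizontal bars, n = 3), on an axis that is linear up to 1 and logarithmic above. Atu2155 lies near 0.843 RPKM in the metH deletion and Atu0432 near 0.503 RPKM in the metZ deletion, while each is higher in the other mutant than in the wild type; the wild type values of Atu4005 spread from 1.67 to 52.4 RPKM.

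A direct comparison tested whether the mutants differed from each other. Atu0432 was 4561-fold higher in the metH deletion, at 2292 ± 131 RPKM against 0.503 ± 0.0843 RPKM in the metZ deletion (SD, n = 3 each), and Atu1468 was 494-fold higher, at 21514 ± 2671 against 43.6 ± 2.85 RPKM. Atu2155 was 771-fold lower in the metH deletion, at 0.843 ± 0.345 against 649 ± 38.4 RPKM, and Atu1866 was 146-fold lower, at 82.6 ± 18.1 against 12080 ± 790 RPKM. If Atu0432 or Atu2155 is a deleted gene, which is left open, its difference between the mutants holds the deletion itself. The log2 differences were 10.58 (SE 0.08, limma adjusted p = 7.5e-16) for Atu0432, 8.91 (SE 0.11, 7.0e-15) for Atu1468, -8.48 (SE 0.15, 2.0e-13) for Atu2155 and -7.20 (SE 0.16, 2.0e-12) for Atu1866. Atu2155, which fell in the metH deletion, rose in the metZ deletion relative to the wild type (log2 fold change 1.85, limma adjusted p = 2.7e-07). In the same way Atu0432, which fell in the metZ deletion, rose in the metH deletion (1.28, limma adjusted p = 2.7e-07). Atu3419 rose in the metH deletion and fell in the metZ deletion, to 61.3 ± 1.33 RPKM (-2.92, limma adjusted p = 1.3e-12). Atu4642, Atu1866 and Atu1865 rose in both mutants and Atu1468 fell in both, by different amounts.

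Of the 4488 IDs, 719 were higher and 1778 lower in the metH deletion than in the metZ deletion by limma, 55.6% of those tested. At least 2-fold differences were seen in 410 and 1169 of them, and at least 8-fold differences in 73 and 66, which became 101 and 34 under median of ratios scaling and 89 and 37 after quantile normalization. Of the 1405 IDs called against the wild type in the metZ deletion and not in the metH deletion, 1229 differed between the mutants, and of the 206 called in the metH deletion and not in the metZ deletion, 178 did. These IDs were chosen with the same mutant libraries, so a called difference follows in part from that choice. A set of 433 IDs was called in opposite directions in the 2 mutants, and a called difference between them follows nearly by construction. The split of the direct comparison was 1131 higher and 1178 lower under median of ratios scaling (713 and 674 at least 2-fold) and 1183 and 1370 after quantile normalization (622 and 673), and the median log2 difference of -0.48 moved to -0.03 and -0.07. Wild type replicate 3 enters the direct comparison only through the shared estimate of spread. Without it 913 IDs were higher and 2441 lower, and a fit of the 2 mutants alone gave 897 and 2426, each with 427 and 1333 at least 2-fold.

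**Figure D3:**
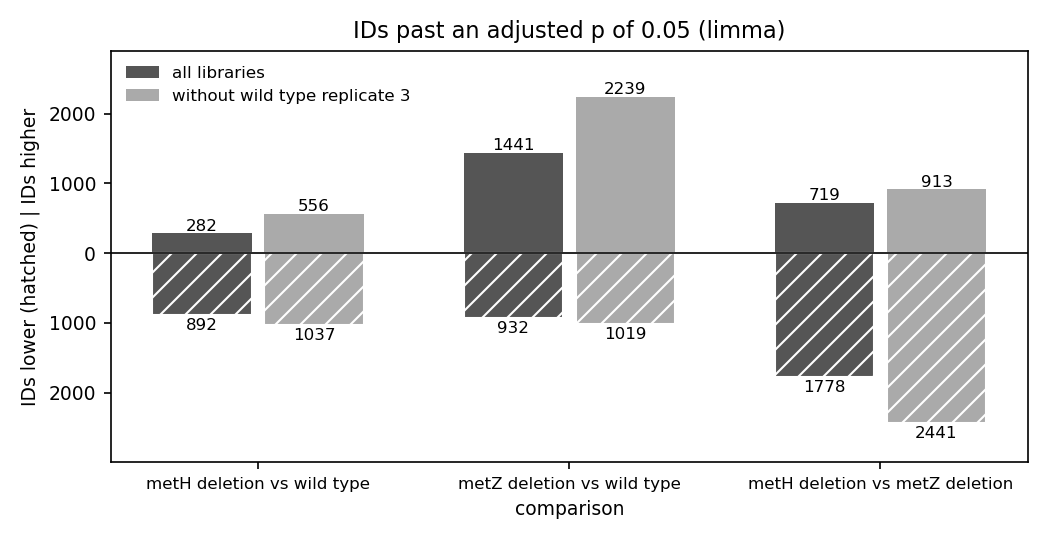
Numbers of IDs past an adjusted p of 0.05 by limma in the 3 comparisons, higher above the 0 line and lower below it (hatched), from all libraries (dark) and without wild type replicate 3 (light). The metH deletion has 282 higher and 892 lower IDs against the wild type from all libraries, and the metZ deletion has 1441 and 932.

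Across the 4488 IDs, which are not independent replicates, the log2 fold changes had a Pearson r of 0.23 (jackknife SE over libraries 0.12) and a Spearman rho of 0.37. Because both comparisons used the same wild type libraries, unchanged groups simulated against those libraries gave a mean r of 0.50 and rho of 0.44 over 100 draws. Without wild type replicate 3 the simulated r was 0.60 and the observed r 0.21. With no effects, r is set by the numbers of libraries in the groups. These simulated values therefore do not measure how far real effects agree. At a mean RPKM of at least 10, r was 0.13 and the covariance 0.109, and the covariance was 0.12 with a pseudocount of 5. The covariance was 0.186 (jackknife SE 0.176), against a simulated 0.0999, and the difference of 0.0865 was smaller than that SE. The simulation gave all libraries the same spread at an ID, although wild type replicate 3 stood apart. The simulated 0.0999 may therefore understate the part that comes from the shared controls. The covariance was 0.331 without wild type replicate 1 and 0.322 without replicate 2, and without replicate 3 it was 0.144 against a simulated 0.0256. Both mutants were higher at 169 IDs, where independent lists would share 90.5, and both were lower at 366, where independent lists would share 185 (jackknife SE 216 and 94.9). At 88 IDs the metH deletion was higher and the metZ deletion lower (58.6 for independent lists), and at 345 the reverse held (286), with jackknife SEs of 30.7 and 125. These SEs are those of the counts, which moved together with the values for independent lists when wild type replicate 3 was left out. The spread of the excesses themselves was not estimated. Without wild type replicate 3 the counts in the same direction stayed above independent lists, at 395 higher in both (277) and 433 lower in both (235), and those in opposite directions fell below them, at 114 (126) and 442 (517). Simulated unchanged groups shared 0 calls, which follows from their having no effects and gives no value to set these overlaps against. The wild type libraries could not be split into parts of at least 2, so part of the excess may come from the shared controls. Independent lists also treat every ID as equally likely to be called. Below 10 RPKM, however, 0 of 942 IDs were higher and 7 lower in the metH deletion, and 13 and 39 in the metZ deletion. At 200 RPKM or more these numbers were 178 and 431 of 943, and 489 and 343. Part of the excesses, in the same and in opposite directions, may therefore come from level, and values within levels were not computed. The number lower in the metH deletion and higher in the metZ deletion was 59 under TMM and 40 under median of ratios scaling, and that lower in both was 100 and 107. Fewer IDs were lower in the metH deletion under these scalings, 199 and 192 against 892. Values for independent lists were not computed there, so a smaller overlap is not by itself a weaker agreement.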

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

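The tests of wild type replicate 3 and of its part in the metH and metZ comparisons were chosen after the result was seen, and median of ratios scaling without that library and leaving out the 10 most abundant IDs were added after the data were seen, with their bounds written before their values; the other splits of the libraries were planned.

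The mutants differed in their effect against the wild type at IDs that the direct comparison tested. At 433 IDs the calls went in opposite directions, for which a called difference between the mutants follows nearly by construction. Of these, 345 were lower in the metH deletion and higher in the metZ deletion. That number was 40 under median of ratios scaling, where fewer IDs were called lower in the metH deletion (192 against 892). The effect of the metH deletion minus that of the metZ deletion was 5.60 on the log2 scale for Atu3419, 1.67 for Atu4642, -8.48 for Atu2155, -7.20 for Atu1866, -6.63 for Atu1865, 8.91 for Atu1468 and 10.58 for Atu0432. For Atu4005 it was -3.37, with 0 reads in the metH deletion libraries and 4 to 6 in each metZ deletion library. Whether Atu2155 and Atu0432 are the deleted genes is left open, and their values would then hold the deletion itself. Groups of 3 libraries were not tested for outlying samples.

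Reads outside the listed IDs, the gap between each recovered total and the reads of all IDs, were 0.555 ± 0.0174% of the total in the metH deletion, above the 0.346 ± 0.0284% of the wild type, and 0.0871 ± 0.0034% in the metZ deletion (SD, n = 3 each). The differences were not tested.

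The limma calls were counted in each of the 10 splits of the 6 libraries of a comparison into 3 and 3. As large a count came in 1 of 10 splits, the real one, in each comparison: 1174 calls for the metH deletion, 2373 for the metZ deletion and 2497 between the mutants, with a highest other count of 0 in all 3. With 10 splits a share under 0.05 cannot be reached.

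The first pattern is wild type replicate 3, which lay above the other wild type libraries by a median of 19.5 RPKM at IDs of 2 to 5 RPKM and below them, at a median ratio of 0.895, above 2000 RPKM. Reads of a deletion library mixed in are argued against, because the same low IDs reached a median of at most 4.13 RPKM in a deletion group, under the excess of 19.5 RPKM. Shallower sequencing is argued against too, since the library with the fewest reads had 0.184 of the median of wild type replicate 3 at these IDs. An even background of reads over all genes remains a candidate explanation: the excess at 20 to 50 RPKM was 0.953 of that at 2 to 5 RPKM, and a background of that size would take 8.47% of the reads, against a drop of 10.5% at the most abundant IDs. What such reads would come from was not tested, and no biological explanation was tested, as no label sets this library apart from its group.

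The second pattern is the excess of lower over higher calls in the metH deletion, 76.0% of calls. The raised low IDs of wild type replicate 3 are argued against as the whole cause, as 65.1% of calls were still lower without that library. They may account for part of the share. Without that library higher calls rose from 282 to 556, but lower calls did not fall and rose from 892 to 1037. Under median of ratios scaling without that library the share was 53.3%. Such a scaling centres the bulk of IDs and so removes a wide shift whatever its cause, and this share cannot decide. Centring does not fix the share, which was 25.6% under TMM with all libraries, at a median log2 fold change of 0.0030. Rescaling with the 10 most abundant IDs left out gave 82.1%, and 75.4% without that library. An effect of the scaling and a wide fall in transcript levels in the metH deletion cannot be told apart, since the files hold no measure of total RNA per cell. A biological effect of the deletion stays open.

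The third pattern is the excess of higher over lower calls in the metZ deletion, 60.7% of calls. Without wild type replicate 3 the share was 68.7%, with 2239 IDs higher and 1019 lower. The raised low IDs of that library are argued against as the source. A raised wild type level makes the deletion look lower, which is opposite to this excess. The larger share on leaving the library out follows by construction and adds nothing to that. The 10 most abundant IDs took 19.1 ± 3.19% of wild type reads and 7.84 ± 1.36% of metZ deletion reads (SD, n = 3), and with them left out the share was 53.1% with all libraries and 60.4% without wild type replicate 3. These values lie on either side of the bounds written down before, and reading them together was chosen after both were seen, so that a few abundant IDs may account for part of the excess and cannot be told apart from a wide rise. Median of ratios scaling without that library gave 50.8%. As its centring removes a wide shift whatever the cause, this share cannot decide, and an effect of the deletion stays open.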

How the results depend on the processing

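The alternatives with voom, the 10 most abundant IDs left out, or median of ratios or those IDs left out without wild type replicate 3, and the overlaps under TMM and median of ratios, were chosen after seeing the data. Of 296 values of named IDs under alternatives 294 kept direction and call, 2 (both Atu4005) kept direction only and 0 reversed. Where no value is given below, counts of calls with no minimum fold stayed within 1.5 times. At 2-fold or more the metH split (96 and 128) was 179 and 40 under TMM, 160 and 48 under median of ratios, 144 and 65 after quantile normalization, 144 and 81 under median of ratios without wild type replicate 3, 90 and 194 with abundant IDs left out and 101 and 201 without wild type replicate 1, and the direct one (410 and 1169) was 747 and 700 under median of ratios without wild type replicate 3. For the metH deletion, higher IDs (282) became 577 under TMM, 585 after quantile normalization, 660 with arrayWeights, 743 under median of ratios without wild type replicate 3, 437 with abundant IDs and that library left out, and 96 at 2-fold or more; lower IDs (892) became 199 under TMM, 192 under median of ratios, 1340 with abundant IDs and that library left out, and 128 at 2-fold or more. For the metZ deletion, higher IDs (1441) became 2341 with arrayWeights and 890 at 2-fold or more, and lower IDs (932) 1545 under median of ratios without wild type replicate 3 and 591 at 2-fold or more. Between the mutants, higher IDs (719) became 1131 under median of ratios, 1183 after quantile normalization, 1556 under median of ratios without wild type replicate 3 and 410 at 2-fold or more, and lower IDs (1778) 1178 and 1169 under the first and last of these. IDs higher in both (169) became 365 after quantile normalization and 386 under TMM, and IDs lower in both (366) 100 under TMM and 107 under median of ratios. IDs higher in metH and lower in metZ (88) became 161 after quantile normalization, and the reverse (345) 186 after it, 59 under TMM and 40 under median of ratios. Leaving out each library gave 229 to 556 IDs higher in the metH deletion, 1322 to 2239 higher in the metZ deletion and 136 to 395 higher in both, the top of each range without wild type replicate 3. The arrayWeights fit gave wild type replicate 3 a weight of 0.0355, against 0.662 to 2.85 for the other libraries. Its counts are thus close to those of leaving that library out. Fewer IDs at 2-fold follow from the stricter threshold, and otherwise the cause was not tested.

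The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.077 to 0.037 and 1 of 9 libraries was closest to its own number. With the replicate block 270 and 827 IDs were called in the metH, 1419 and 904 in the metZ and 694 and 1748 in the direct comparison. At 8-fold or more the metZ split (60 and 85) was 93 and 83 with arrayWeights. Gene list alternatives were not run, as no list could be matched. Below 10 RPKM few of 942 IDs were called from all libraries, but 270 were higher and 77 lower in the metZ comparison without wild type replicate 3, so depth alone did not limit these calls.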

Other observations

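The tests below were all chosen after the data were seen. Changes came in runs of consecutively numbered IDs, whose positions the files do not give. Counting IDs called at 2-fold or more in the same direction, the metZ deletion had 63 runs of at least 4, with 325 IDs, where 2 sets of 1000 shuffles of the ID order gave at most 17 runs and 72 IDs, and without wild type replicate 3 it had 100 runs with 490 IDs, where shuffles gave at most 32 and 135. The metH deletion had 13 such runs with 79 IDs, and 12 with 76 IDs without that library, where shuffles gave at most 1 run. With all libraries, the longest runs held 14 IDs, lower in the metZ deletion, with a median log2 fold change of -5.02 in the first of the 2 of that length, and 13 IDs, higher in the metH deletion with a median of 1.62. Atu1865 and Atu1866 belonged to a run of 7 IDs that rose in the metZ deletion by a median of 4.88. Atu3419 belonged to a run of 7 that rose in the metH deletion by a median of 2.27, and to a run of 8 that fell in the metZ deletion by a median log2 change of -3.61. Atu0432 in the metZ deletion and Atu2155 in the metH deletion, by contrast, stood alone, with no consecutive ID called at 2-fold in that direction. So did Atu4642, Atu4005 and Atu1865 in the metH deletion. Grouped by the leading digit of the zero-padded number, 4 of 7 groups passed the camera test of limma in the metZ comparison with its preset correlation: digit 1 toward higher levels (adjusted p = 0.0019, median log2 fold change 0.43) and digits 3, 4 and 5 toward lower ones (adjusted p = 0.0060, 0.0024 and 0.0011). The 176 tested IDs of digit 5 had a median log2 fold change of -0.62 in the metZ deletion, against 0.04 over all tested IDs, and of -0.05 against 0.40 without wild type replicate 3. The medians of digits 3 and 4 were -0.36 and -0.39, and turned to 0.19 and 0.21 without that library. Digits 3 and 4 were then lower only relative to the other IDs. All 4 calls were lost with an estimated correlation (adjusted p = 0.867 for each, and 0.137 to 0.205 without wild type replicate 3).

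The hypothesis that changes were placed by chance along the ID numbers was tested by the correlation of fold changes between consecutive IDs. Over 4228 pairs in the metZ comparison r was 0.464, and 0.441 without wild type replicate 3, while shuffled orders gave at most 0.0504, which argues against chance placement. In the metH comparison r was 0.475, and 0.456 without that library, against at most 0.0543. Genes in shared transcription units would give such a pattern and may be its source, but reads that span adjoining genes were not separated from it and no annotation of such units was used.

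Of the listed IDs, 916 (16.8%) were at 0 in all 9 libraries, and 768 of them lay in 15 stretches of at least 10 consecutive IDs, the longest of 202. Of the 916, 194 were the whole of the IDs whose number has the leading digit 6, and 363 were among the 541 with the digit 5. The hypothesis that these genes are present in the strain and silent was tested with the even background of wild type replicate 3, which would then reach them. Of the 921 IDs at 0 in the other 8 libraries, 5 (0.543%) had reads in that library, whereas of the 525 IDs whose highest value in those libraries lay above 0 and below 5 RPKM, 515 (98.1%) did, and of the 47 whose highest value lay below 1 RPKM, 41 (87.2%) did. This argues against present and silent genes for most of these IDs, as long as the background is even. A difference between the sequenced strain and the reference behind the ID list may account for it, and reads left out because they match several places remain open too.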
